A study of Mus musculus with 4 samples.

How the data were processed

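Single-cell RNA sequencing was done on hearts of 6-week-old mice whose mothers had eaten, through pregnancy and lactation, either a diet rich in resistant starch or a comparison diet. Per the labels, hearts were perfused with 2 mg/mL collagenase IV and 1 mg/mL dispase II. Cells were then sorted as live, metabolically active and nucleated, and captured with the 10x Genomics 3′ v2 chemistry, again per the labels. The sort sets which cells could be sampled, so shares of cell classes describe sorted cells and not the intact heart. The labels give 4 libraries, 2 from offspring of high-fibre dams (high_fibre) and 2 from offspring of control dams (control_diet). The series text describes the comparison diet as low in resistant starch. The labels do not say how many animals went into a library.

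The authors deposited, for each library, whole-number UMI counts per gene and cell barcode. Per the submitters' processing notes these came from Cell Ranger 3.1.0 with the mm10 genome build. The deposited count matrices held 26765 barcodes and 31053 genes, and the barcode with the fewest UMIs held 500, so empty droplets had been left out before deposit. Library totals ran from 27577599 UMIs (control_diet 2) to 69600492 UMIs (high_fibre 2). No deposited cell annotation was used here, and cell classes were rebuilt from the counts, so they can differ from those of the study. Gene coordinates come from GENCODE M21 on GRCm38 (the mm10 assembly), matched by Ensembl ID for 30934 of 31053 genes (99.6%). They are 1-based. Symbols shared by several IDs (71) were kept apart by ID.

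Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 20% of UMIs from mitochondrially encoded genes. Doublets were scored within each library by the share of simulated doublets among a cell's nearest neighbours, with 2 simulated doublets per cell. The highest scoring 0.8% per 1000 barcodes of that library were removed, which took 2.36% to 7.23% of barcodes. These steps left 22346 cells. Counts were scaled to 10000 per cell and log transformed, and the 2000 most variable genes gave 30 principal components. A graph of 15 nearest neighbours was clustered with the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, seed 20) with no batch integration. It gave 30 clusters. Figures were drawn with matplotlib 3.10.9.

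Marker genes of each cell type, the 39 gene lists, the tests and the rule for named genes were fixed before the data were examined. A cluster took the name of the class whose markers led it, as fold against all other cells with a pseudocount of 5 CPM. At least 3 markers had to be detected in 25% of its cells. A cluster stayed unnamed when its top 10 genes held more markers of another class. It also stayed unnamed when a second, unrelated class had at least 3 detected markers and a mean marker log2 fold above 2. The last case was a median UMI count under 1/3 of its libraries' with no own marker among its top 10 genes. This naming rule was set after the clusters were seen, and was revised once because its first version misnamed fibroblast clusters. It named 26 of 30 clusters. The other 4 entered no gene test, and their shares are given with those of the classes. Classes with at least 20 cells in every library were tested (8 classes), and those with at least 100 in every library are the main classes (4). Sexes were assigned to single cells from Xist and Y-linked UMIs, because the labels give no sex.

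UMI counts were summed per library and class, so that the library and not the cell was the replicate. Genes passing filterByExpr at a minimum count of 10 were tested with the quasi-likelihood test of edgeR 4.0.16 (robust, TMM normalization, R 4.3.3). Benjamini-Hochberg adjustment was made within each class, and 0.05 was the threshold. Fold changes are log2 of high_fibre over control_diet, and CPM values are library-normalized counts scaled to 1e6. Cell numbers per class and per cluster were tested with the same edgeR test with the library's kept cells as the total. Gene lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, which compares list genes with all other tested genes. The same test with the correlation estimated from the data, and fry, which tests whether the genes of a list move one way, were run beside it. Diet effects of a pair of main classes were compared with limma (trend, robust, prior count 2) on the within-library difference of log2 CPM. The repeat numbers of the labels were not taken as pairs, since nothing in the labels says what a number shares. An exact two-sided permutation test of 2 against 2 libraries cannot give a p below 0.333, so none is printed. Counting intervals are exact binomial at 95% and cover counting error only.

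The text names, in each main class, the 12 called genes with the largest rise and the 12 with the largest fall among those with both libraries of a group on one side of both of the other. With fewer than 3 called genes, the 5 smallest unadjusted p in each direction are given as values only. It also names genes called the same way in at least 3 classes, up to 4 members with the largest absolute fold in each list that passed, and Nppa, Myh6, Hba-a1, Xist and Ddx3y where tested. Predicted genes may be summarised by number. Called genes of the smaller classes are named too. A gene with no counts in a group gets a fold computed at a floor of 3 counts over the group.

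The tests were tested on simulated data drawn from the real means and library sizes. With 200 genes changed, edgeR recovered 50.7%, 86.6% and 95.5% of genes changed by 1.5, 2 and 4 fold in fibroblasts. The same folds gave 47.8%, 70.1% and 100% in endothelial cells, 19.4%, 70.1% and 97% in macrophages, and 11.9%, 65.7% and 93.9% in pericytes. Of the called genes, 44 of 199 in fibroblasts and 25 of 170 in endothelial cells were unchanged. In macrophages 19 of 143 were unchanged, and in pericytes 11 of 125. With no gene changed, 20 runs called a median of 9 genes in fibroblasts (0 to 29), 7.5 in endothelial cells (1 to 16), 10 in macrophages (1 to 20) and 1 in pericytes (0 to 5). Camera at the preset correlation recovered 1 of 1 raised list in each main class, and in macrophages also called 1 unchanged list. With an estimated correlation it recovered 0 of 1 in each. The simulated genes were drawn independently of each other. These runs therefore cannot show whether the preset correlation holds for real genes that vary together. A rise of the macrophage share by 2, 4 and 8 fold was recovered in 12%, 38% and 70% of 50 runs.

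Results were also computed with DESeq2 size factors, the DESeq2 1.42.0 test, limma-voom, no low-count filter, the repeat number as a block, no doublet removal, a mitochondrial maximum of 10%, a minimum of 1000 UMIs, thinned counts, clustering at resolution 0.5, TMM on cell numbers, a prior count of 0.5 and leaving out each library in turn. Fits without a library repeated the low-count filter, so a list's median there can be over other members than with all libraries. Cells of each sex alone, low-UMI clusters left out, immune-positive cells left out and the comparison of sexes were added after the data were seen.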

Results

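Hearts of 6-week-old offspring were profiled cell by cell to ask how the fibre content of the mother's diet, eaten through pregnancy and lactation, relates to the cells of the young heart. All offspring had moved to the same standard chow at 3 weeks. The data were 4 droplet libraries, 2 from offspring of high-fibre dams and 2 from offspring of control dams. They held 56582577 and 69600492 UMIs in the high_fibre libraries 1 and 2, and 59317334 and 27577599 in the control_diet libraries 1 and 2. After filtering, 6356, 7546, 5811 and 2633 cells remained in that order, with median depths of 5799.5, 6112, 7686 and 7475 UMIs per cell. Median mitochondrial shares were 4.56% to 4.77%. The labels do not say that the libraries are separate animals. The p-values of genes, shares and class differences therefore measure the spread between these libraries, which may be technical. Camera p-values at the preset correlation set the genes of a list against other genes and take their correlation as fixed. They do not measure how well the libraries agree.

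Each library held cells of both sexes. Cells with Y-linked and no Xist UMIs made up 64.0% (62.6% to 65.4%, exact 95% interval) of the sexed cells of high_fibre 1 and 39.2% (38.0% to 40.5%) of high_fibre 2. The shares were 25.4% (24.2% to 26.7%) in control_diet 1 and 43.1% (40.9% to 45.2%) in control_diet 2. Over all kept cells, Xist, the RNA of the inactive X chromosome, stood at 293, 586, 739 and 440 CPM in the same order. Ddx3y, a Y-linked helicase, stood at 72.3, 40.3, 28.3 and 43.2 CPM. Of the cardiomyocyte transcripts, Myh6, the cardiac myosin heavy chain, stood at 2.52 to 6.46 CPM and Nppa, atrial natriuretic peptide, at 0.20 to 0.34 CPM. Others, with Myl2, Mb and Myl3 first, led the unnamed cluster 24 of 174 cells, which also carried endothelial markers. Hba-a1, an alpha globin, ran from 155 to 347 CPM.

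The cells fell into fibroblast-like, endothelial-like, macrophage-like and pericyte-like classes, with smaller classes of B, T, NK, endocardial, smooth muscle, monocyte, Schwann, lymphatic, neutrophil and cardiomyocyte cells. Fibroblasts made up 26.2% ± 0.75 of cells in the high_fibre libraries and 26.3% ± 6.19 in the control_diet libraries (SD, n = 2), and endothelial cells 25.9% ± 2.94 and 32.6% ± 9.34. Macrophages, the resident phagocytes of the tissue, stood at 17.0% ± 0.90 in high_fibre and 13.6% ± 1.73 in control_diet, and B cells at 5.42% ± 1.77 and 3.48% ± 1.16. Pericytes, which wrap capillaries, stood at 5.10% ± 0.30 and 4.54% ± 0.34. Only 19 cells were named cardiomyocytes, the unnamed cluster 24 not counted. Neutrophils varied most within a group relative to their mean share, from 0.07% in high_fibre 2 to 1.09% in high_fibre 1.

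No class differed between the diets beyond the spread between libraries. The edgeR test called 0 of 18 classes, 4 unnamed clusters counted as classes included, and 1 class had an unadjusted p under 0.05. That one was unnamed cluster 11, led by Apln, Kit and Mest, with endothelial markers, at 2.33% ± 0.09 and 5.05% ± 2.05 of cells (adjusted p = 0.504, edgeR). The macrophage share had a log2 ratio of 0.32 (SE 0.37, adjusted p = 0.803), higher in both high_fibre libraries than in both control_diet libraries. The other unnamed clusters stood, in high_fibre and control_diet, at 7.49% and 3.64% (cluster 5), 0.76% and 0.84% (cluster 24), and 0.19% and 0.39% (cluster 28). Of the 30 clusters 0 were called by edgeR, and 3 had an unadjusted p under 0.05. These were cluster 11, the B-cell cluster 18 of low UMI count (1.82% ± 0.08 and 0.74% ± 0.13) and the endothelial cluster 14 led by the interferon-induced genes Ifi44, Rsad2 and Ifit2 (1.65% ± 0.18 and 3.70% ± 1.38), each with adjusted p = 0.320. On simulated data a 2-fold rise of the macrophage share was called in 12% of runs, so a difference of that size would rarely be called here.

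**Figure D1:**
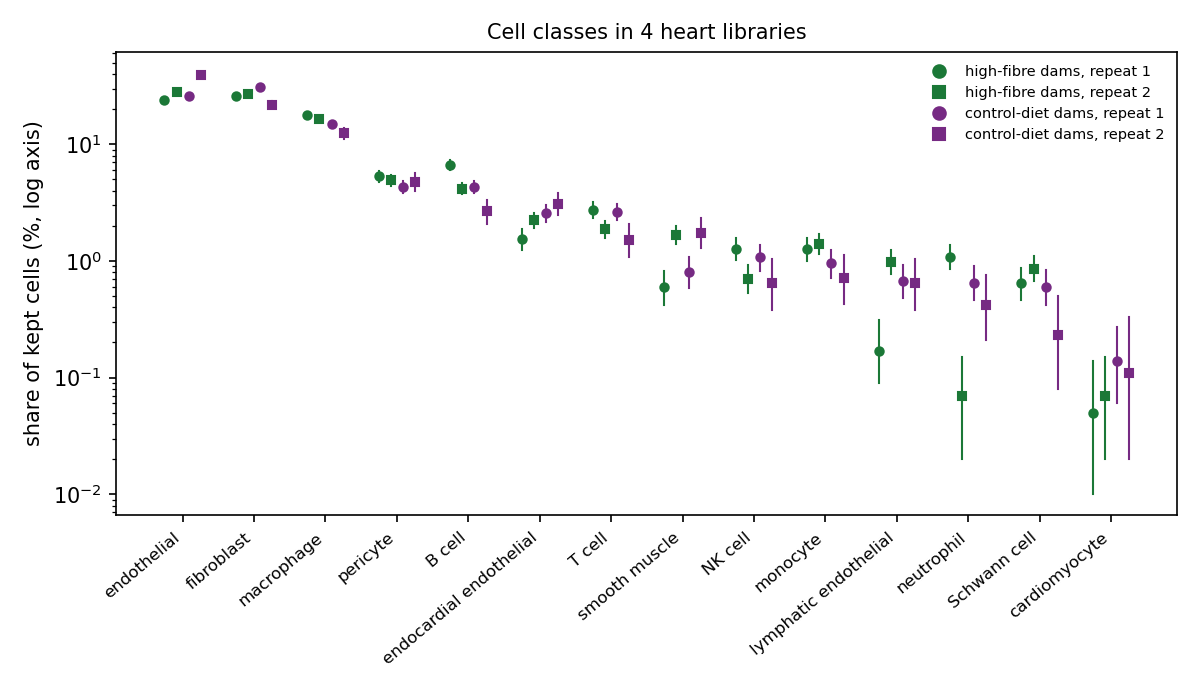
Share of kept cells per class (percent, log axis) in each of the 4 libraries, with exact 95% binomial intervals for counting error; circles are repeat 1, squares repeat 2. Macrophages lie at 16.4% and 17.6% in the high_fibre libraries and at 12.4% and 14.8% in the control_diet libraries.

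Fibroblasts of high_fibre offspring carried less RNA of a small set of endoplasmic reticulum proteins that cells make when unfolded protein accumulates. Sdf2l1, a partner of the chaperone BiP, stood at 37.2 ± 1.17 CPM against 73.9 ± 1.5 CPM in control_diet (SD, n = 2), a log2 fold of −0.99 (SE 0.0868, adjusted p = 0.0101, edgeR). Creld2 fell by 0.92 on the log2 scale (adjusted p = 0.0247), from 72.1 to 38.1 CPM, and Manf, a secreted stress-response factor of the same compartment, fell by 0.74 (adjusted p = 0.043), from 407 to 244 CPM. Both high_fibre libraries lay below both control_diet libraries for all 3 genes. In GRCm38 Sdf2l1 lies on the minus strand of chromosome 16 (17130138 to 17132383), Creld2 on the plus strand of chromosome 15 (88819646 to 88826683) and Manf on the minus strand of chromosome 9 (106838312 to 106891979). All are protein coding, and the interval of Manf overlaps Rbm15b on the same strand, so counts the pair share are uncertain.

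These 3 were the genes called among 13276 tested in 6008 fibroblasts, 0 higher and 3 lower, with 877 at an unadjusted p under 0.05 against 664 by chance. The 2 groups were apart for 35.7% of genes, where chance gives 33.3%. Other tools called more: DESeq2 42 genes (28 higher, 14 lower) and limma-voom 5. Simulations with no change called a median of 9 genes (0 to 29), so a count of 3 does not by itself stand above chance. Leaving out control_diet 1 raised the adjusted p of Sdf2l1, Creld2 and Manf to 0.209, 0.323 and 0.362, and leaving out control_diet 2 to 0.0817, 0.164 and 0.153, with log2 folds of −0.69 to −1.01. Without high_fibre 1, 18 genes were called, and without high_fibre 2, 218. Among the genes named in every comparison, none was called: Xist had a log2 fold of −0.33, Ddx3y 0.63, Myh6 −0.12 and Hba-a1 3.68 (adjusted p of 0.913 to 0.987).

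The genes of cholesterol synthesis were lower as a group in fibroblasts of high_fibre offspring, 18 of 22 measured members below 0 with a median log2 fold of −0.50 (camera adjusted p = 7.23e-22, adjusted p = 0.539 with an estimated correlation). None of the 22 was called over all genes, and 12 were lower when adjusted over the list alone. Fdft1, squalene synthase, had a log2 fold of −0.92 (SE 0.195, adjusted p = 0.298), Mvd −0.78, Idi1 −0.75 and Cyp51, lanosterol demethylase, −0.74. The fibrillar and network collagens, the main fibres of cardiac matrix, had 16 of 17 members below 0 at a median of −0.19 (camera adjusted p = 7.15e-07, adjusted p = 0.539 with an estimated correlation). Col18a1 had −0.47, Col14a1 −0.26, Col1a1 −0.25 and Col3a1 −0.23, with 0 called over all genes and 1 lower adjusted over the list alone. The interferon response list fell slightly, with 24 of 35 members below 0 and a median of −0.10 (camera adjusted p = 0.0348, adjusted p = 0.582 with an estimated correlation; 0 adjusted over the list alone).

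Heat shock genes rose together in fibroblasts, 16 of 20 above 0 at a median of 0.23 (camera adjusted p = 8.19e-07, adjusted p = 0.539 with an estimated correlation), with 0 called over all genes and 2 higher adjusted over the list alone. Hspa1a had a log2 fold of 1.14, Hspa1b 1.09, the small chaperone Hspb1 1.06 and Dnajb1 0.86. Hspa1a and Hspa1b are near-identical copies between which counting can split reads, so each one's level is uncertain. Complement genes rose at a median of 0.13, 12 of 17 above 0 (camera adjusted p = 2.05e-06, adjusted p = 0.539 with an estimated correlation), with C4b at 1.32 and C3, the central complement protein, at 0.61. Glucocorticoid-responsive genes rose at a median of 0.25, 17 of 19 above 0 (camera adjusted p = 2.05e-06, adjusted p = 0.539 with an estimated correlation), with Fkbp5 at 0.74 and Sult1a1 at 0.71. Cytokines and chemokines rose at a median of 0.29, 24 of 27 above 0 (camera adjusted p = 2.05e-06, adjusted p = 0.539 with an estimated correlation), with Ccl6 at 1.79. Each of these 3 lists had 0 genes called over all genes. Adjusted over the list alone, 3, 1 and 1 members were higher.

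Other lists that passed camera in fibroblasts hold transcripts of other cell types. Resident macrophage genes had a median of 0.32 (adjusted p = 0.000527), recruited macrophage genes 0.54 (0.00986), MHC class II genes 0.55 (0.00159), T cell genes 0.30 (0.0155), B cell genes 0.29 (0.0272), globin and other erythroid transcripts 3.24 (0.00282), and endothelial identity genes 0.13 (0.039), all with adjusted p of 0.539 to 0.607 with an estimated correlation. Lists of general function were ribosomal proteins at 0.08 (adjusted p = 0.000936), lipid handling and PPAR targets at 0.12 (0.00404) and immediate early genes at 0.12 (0.0272). These 10 lists had adjusted p of 0.539 to 0.785 with an estimated correlation and 0 members called over all genes. Adjusted over the list alone, MHC class II had 3 higher members and 1 lower, B cell genes 2 higher, and T cell and lipid genes 1 each. Of the 17 lists that passed among 35 tested, 5 did so without each library in turn: cholesterol synthesis, collagens, heat shock, cytokines and complement. Leaving out each library in turn, the medians that moved by over 1.5 times (a bound chosen while writing, after the results were seen) ran as follows: collagens −0.24 to −0.12, heat shock 0.02 to 0.36, glucocorticoid genes 0.09 to 0.52, cytokines 0.28 to 0.57, complement 0.12 to 0.32, resident macrophage genes 0.11 to 0.42, ribosomal proteins 0.05 to 0.12, MHC class II 0.34 to 0.72, erythroid transcripts 1.52 to 4.05, recruited macrophage genes 0.34 to 0.60, T cell genes 0.00 to 0.64, immediate early genes −0.08 to 0.33, B cell genes 0.16 to 0.53, interferon genes −0.17 to −0.03 and endothelial identity genes 0.02 to 0.19. Without high_fibre 1 the glucocorticoid, T cell and B cell lists (adjusted p = 0.274 each) and the endothelial list (0.116) missed the threshold, the immediate early list turned to −0.08, and the heat shock median dropped to 0.02. Without high_fibre 2 the MHC class II (0.329), resident macrophage (0.354), ribosomal (0.109), lipid (0.107), endothelial (0.13) and interferon (0.628) lists missed it. Without control_diet 1 the erythroid (0.0671) and recruited macrophage (0.0504) lists missed it, and without control_diet 2 the immediate early (0.16), resident macrophage (0.0556), B cell (0.0883), endothelial (0.615) and interferon (0.162) lists.

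In endothelial cells of high_fibre offspring more RNA was counted of macrophage and MHC class II genes and of Igkc and Coro1a. The same held for 1 tight-junction gene and 1 lipid-metabolism gene, while less was counted of a peptide transporter. Whether the immune RNA was made by these cells or was free RNA in the droplets cannot be told. Igkc was the leading gene of the B-cell cluster 10, so its counts here need not be a change of endothelial cells. Cd74, the invariant chain of MHC class II, stood at 65.2 ± 3.05 CPM against 26.7 ± 2.90 CPM (SD, n = 2), a log2 fold of 1.28 (SE 0.122, adjusted p = 0.000187, edgeR). H2-Eb1 rose by 1.40 and H2-Aa by 1.31, both MHC class II chains. The complement subunits C1qa and C1qb, made by macrophages, rose by 1.55 and 1.28, Tyrobp, an adaptor of myeloid receptors, by 1.5, and Pf4 by 1.03. Coro1a, an actin regulator of leukocytes, rose by 2.14, Igkc, the immunoglobulin kappa constant region, by 1.72, and the chemokine Cxcl10 by 1.55. Their adjusted p ran from 0.000719 to 0.044. In fibroblasts Igkc had a log2 fold of 1.27 and the sum of Cd74, H2-Aa, H2-Ab1 and H2-Eb1 0.71, neither called (adjusted p = 0.177 and 0.205, edgeR).

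Claudin 5 (Cldn5), a protein of endothelial tight junctions, rose by 0.74 (SE 0.116, adjusted p = 0.0186), from 618 ± 45.9 to 1031 ± 157 CPM (SD, n = 2). Angptl4, a PPAR target that inhibits lipoprotein lipase, rose by 0.78 (SE 0.133, adjusted p = 0.0373), from 40.5 to 69.2 CPM. Slc15a2, a proton-coupled transporter of small peptides, fell by 3.49 (SE 0.325, adjusted p = 0.000187), from 10.5 ± 0.724 to 0.897 ± 0.196 CPM (SD, n = 2). Igfbp5, which binds insulin-like growth factors, fell by 0.68 (adjusted p = 0.0427), and the predicted gene Gm3164, which overlaps a similar gene, fell by 1.79 (adjusted p = 0.0427). On GRCm38 Cd74 lies on chromosome 18 (60803848 to 60812652), Cldn5 on chromosome 16 (18776847 to 18778262), Slc15a2 on chromosome 16 (36750177 to 36784962) and Angptl4 on chromosome 17 (33773750 to 33781830), all protein coding.

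In all, 15 of 11429 genes were called in 6167 endothelial cells, 12 higher and 3 lower, with the groups apart for 33.5% of genes against 33.3% by chance. At an unadjusted p under 0.05 there were 572 genes, against 571 by chance. Simulations with no change called a median of 7.5 genes (1 to 16). Cd74 and Slc15a2 kept their calls without each library in turn. Without high_fibre 1, 6 of the 15 genes remained called: Igkc moved to adjusted p = 0.0508, Pf4 0.0508, H2-Eb1 0.103, Cxcl10 0.136, H2-Aa 0.176, Angptl4 0.176, Gm3164 0.379, Cldn5 0.432 and Igfbp5 0.685. Without high_fibre 2, 4 remained: Igfbp5 moved to 0.0737, H2-Aa 0.0788, C1qa 0.0845, C1qb 0.124, Cxcl10 0.15, Coro1a 0.157, H2-Eb1 0.207, Tyrobp 0.303, Gm3164 0.377, Pf4 0.392 and Angptl4 0.393. Without control_diet 1, Gm3164 lost its call (0.0729) and 113 genes were called in all, and without control_diet 2, 80. Xist had a log2 fold of −0.68, Ddx3y 1.08, Myh6 −0.39 and Hba-a1 1.67, all uncalled (adjusted p = 0.991 each).

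**Figure D2:**
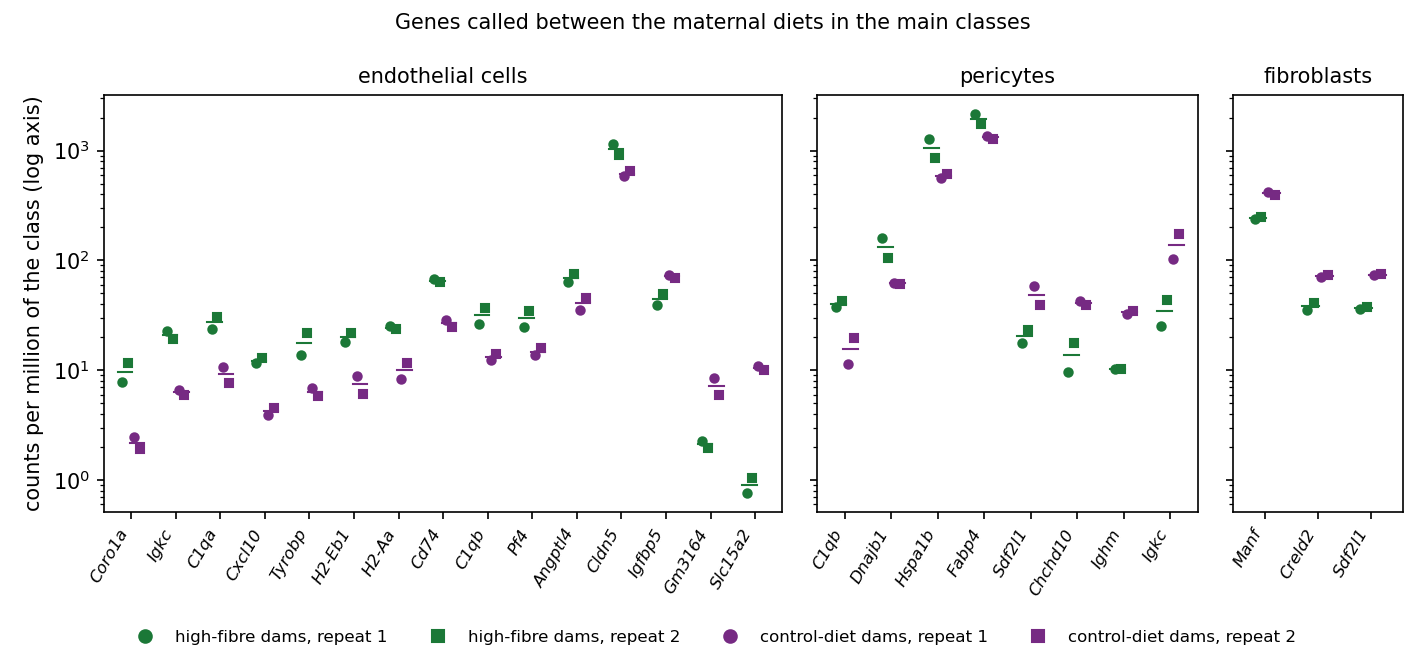
Normalized counts (CPM of the class, log axis) of every gene called between maternal diets in endothelial cells (15 genes), pericytes (8) and fibroblasts (3); points are single libraries, circles repeat 1 and squares repeat 2, and dashes are group means of 2 libraries. Slc15a2 lies at 0.76 and 1.04 CPM in the high_fibre libraries and at 11 and 9.97 CPM in the control_diet libraries of endothelial cells.

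MHC class II genes led the lists in endothelial cells, 9 of 10 above 0 with a median log2 fold of 1.18 (camera adjusted p = 4.03e-27, adjusted p = 0.363 with an estimated correlation). Of these, 3 were called over all genes and 6 were higher adjusted over the list alone, while H2-DMa at 1.63 and Cd86 at 1.38 were not called. Complement genes rose at a median of 0.40, 8 of 12 above 0 (camera adjusted p = 2.19e-09, adjusted p = 0.439 with an estimated correlation), with C1qa and C1qb called, C3 at 1.52 and C1qc at 1.27 not called; 4 were higher adjusted over the list alone. Recruited macrophage genes (median 0.78, adjusted p = 1.33e-07) and resident macrophage genes (0.49, 6.65e-07) rose, as did cytokines (0.38, 2.84e-06), each with adjusted p of 0.363 to 0.439 with an estimated correlation. Over all genes they had 1, 1 and 0 called members, and adjusted over the list alone 1, 3 and 4 higher. In macrophages the C1q genes were not called, and their sum stood at 15880 to 17271 CPM. The 3 C1q genes summed to 60.6 and 89.2 CPM in endothelial cells of the high_fibre libraries and to 29.8 and 28.6 CPM in the control_diet libraries, a log2 fold of 1.36 (SE 0.156, adjusted p = 0.00629). Their sum had log2 folds of 0.91 (SE 0.278, adjusted p = 0.667) in fibroblasts and 1.33 (SE 0.226, adjusted p = 0.01) in pericytes. Col1a1, Col1a2, Col3a1 and Dcn, transcripts of fibroblasts, summed in endothelial cells to 131 and 158 CPM in the high_fibre and 108 and 65.3 CPM in the control_diet libraries, a log2 fold of 0.73 (SE 0.289, adjusted p = 0.99).

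The interferon response fell in endothelial cells, 31 of 35 members below 0 with a median of −0.19 (camera adjusted p = 1.02e-08, adjusted p = 0.439 with an estimated correlation). Ifit3b had −0.62, Oas1a −0.57 and Ifit3 −0.49, none called over all genes, while Cxcl10, on the same list, rose; adjusted over the list alone 9 were lower and 2 higher. The endothelial class holds cluster 14, led by interferon-induced genes, which made up 1.65% of cells in high_fibre and 3.70% in control_diet (adjusted p = 0.320). Lipid handling and PPAR targets rose, 23 of 27 above 0 with a median of 0.16 (camera adjusted p = 1.69e-06, adjusted p = 0.363 with an estimated correlation, fry adjusted p = 0.0217, with fry of the other lists not given). Beside Angptl4 they included Lpl, lipoprotein lipase, at 0.47, Pdk4 at 0.45 and Plin2, a lipid droplet coat protein, at 0.42, with 3 higher adjusted over the list alone. Heat shock genes rose at a median of 0.54, 17 of 19 above 0 (camera adjusted p = 6.65e-07), and glucocorticoid-responsive genes at 0.32, 14 of 17 above 0 (1.96e-06), with adjusted p of 0.572 and 0.439 with an estimated correlation. Erythroid transcripts rose at a median of 1.36 (4.29e-06), and collagens at 0.23 (0.0292), with adjusted p of 0.557 and 0.572 with an estimated correlation. Venous and endocardial identity genes fell at a median of −0.15 (0.00211), with Aplnr at −0.55, and cholesterol synthesis genes at −0.17 (0.00226). Both had adjusted p = 0.439 with an estimated correlation. Adjusted over the list alone, glucocorticoid-responsive genes had 3 higher members (1 over all genes), collagens 1 higher and venous genes 1 lower, and heat shock, erythroid and cholesterol genes 0. In all 13 of 33 lists passed. Without high_fibre 1 the heat shock list (median 0.04, adjusted p = 0.16) and the venous list (0.412) missed the threshold, and the medians of the glucocorticoid and erythroid lists dropped to 0.04 (adjusted p = 0.0472) and 0.42. Without high_fibre 2 the resident macrophage (0.169), cholesterol (0.169) and collagen (0.403) lists missed the threshold. Without control_diet 2 the glucocorticoid (0.0704), venous (0.0621) and collagen (0.572) lists missed it. Leaving out each library in turn, the medians that moved by over 1.5 times ran as follows: complement 0.19 to 0.69, recruited macrophage genes 0.45 to 1.65, heat shock 0.04 to 0.91, resident macrophage genes 0.27 to 0.87, glucocorticoid genes 0.04 to 0.33, cytokines 0.20 to 0.57, erythroid transcripts 0.42 to 1.92, venous genes −0.50 to −0.06 and collagens 0.08 to 0.31.

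No gene was called between the diets in macrophages in the main fit. The edgeR test called 0 of 11396 genes in 3542 macrophages, with 379 at an unadjusted p under 0.05 against 570 by chance. DESeq2 called 1 and limma-voom 0. With the repeat number as a block edgeR called 11, though nothing in the labels says what a number shares. The genes with the smallest unadjusted p, given as values only with adjusted p = 1.00, were higher for S100a8, a neutrophil and monocyte protein (log2 fold 3.16), Rbm3, a cold-inducible RNA-binding protein (0.67), and the lectin receptors Clec4b1 (0.66) and Clec12a (0.46). Chil3, a protein of monocytes and alternatively activated macrophages, had 28 UMIs in the high_fibre libraries and 0 in the control_diet libraries. With a floor of 3 counts over the control_diet group it was 4.86-fold higher. The exact 95% interval of its rate ratio, for counting error only, began at 3.70. Lower values were those of Mmp13, a collagenase (−0.76), the Y-annotated Gm47283 (−0.84), Fcer2a, a B-cell IgE receptor (−2.43), Etfbkmt (−1.37) and H1f0, a linker histone (−0.45). Hba-a1 stood at 404 CPM in control_diet 1 and at 6.88 to 17.4 CPM in the other 3 libraries; Xist had a log2 fold of −0.66, Ddx3y 0.83 and Myh6 −0.69. Without control_diet 1, 8 genes were called, and without high_fibre 2, 2.

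As groups, heat shock genes rose in macrophages, 18 of 19 above 0 with a median of 0.64 (camera adjusted p = 1.88e-11, adjusted p = 0.639 with an estimated correlation), led by Hspb1 at 1.98, Hsph1 at 1.53 and Bag3 at 1.24. Lipid handling genes rose at a median of 0.20, 23 of 25 above 0 (camera adjusted p = 7.57e-06, adjusted p = 0.639 with an estimated correlation), with Plin2 at 0.65 and Lpl at 0.58. Recruited macrophage genes rose at a median of 0.21, 12 of 15 above 0 (camera adjusted p = 8.82e-05, adjusted p = 0.639 with an estimated correlation), with Fn1, fibronectin, at 0.89. The median was also 0.21 with Chil3 at the floor. Cell cycle genes fell at a median of −0.54, 19 of 26 below 0 (1.41e-05, adjusted p = 0.639 with an estimated correlation). Their largest members, Ube2c, Ccnb2, Cenpf and Birc5, were high in control_diet 2 alone, where Ube2c stood at 54.8 CPM against 1.64 to 2.76 CPM in the other 3 libraries. Passing with smaller medians were glucocorticoid-responsive genes (0.22, adjusted p = 0.000679), B cell genes (−0.18, 0.000836), matrix glycoproteins (0.18, 0.0104), imprinted growth genes (0.23, 0.013), matrix crosslinking enzymes (0.16, 0.0184), NF-kappaB targets (0.22, 0.0209), MHC class I genes (−0.13, 0.0331), erythroid transcripts (−4.13, 0.0398) and the interferon response (−0.10, 0.0437). These 9 had adjusted p of 0.639 to 0.698 with an estimated correlation. Over all genes 0 members of the 13 passing lists were called; adjusted over the list alone 1 recruited macrophage gene was higher, 1 B cell gene was lower and no other member passed.

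Only heat shock and lipid handling passed in macrophages without each library in turn. Without control_diet 2, 4 lists passed, and the cell cycle (adjusted p = 0.190), recruited macrophage (0.0522), glucocorticoid (0.427), matrix glycoprotein (0.806), imprinted (0.801, median −0.07), crosslinking (0.633), NF-kappaB (0.806) and MHC class I (0.957) lists were lost, and the interferon list turned to 0.10. Without high_fibre 1 the recruited macrophage (0.260), imprinted (0.258) and crosslinking (0.0994) lists were lost, the interferon list missed the threshold (adjusted p = 0.174), the glucocorticoid list turned to −0.09 and the NF-kappaB list to −0.29. Without high_fibre 2 the B cell (0.202), matrix glycoprotein (0.172), MHC class I (0.201) and interferon (0.0562) lists were lost, and without control_diet 1 the erythroid list turned to 0.11. The heat shock median in macrophages was 0.19 without high_fibre 1 and 0.98 without high_fibre 2. Leaving out each library in turn, the medians that moved by over 1.5 times ran as follows: heat shock 0.19 to 0.98, cell cycle −1.09 to −0.05, recruited macrophage genes 0.05 to 0.61, glucocorticoid genes −0.09 to 0.52, B cell genes −0.45 to −0.23, matrix glycoproteins 0.01 to 0.67, imprinted genes −0.07 to 0.40, crosslinking enzymes 0.05 to 0.55, NF-kappaB targets −0.29 to 0.55, MHC class I genes −0.21 to −0.04, erythroid transcripts −5.55 to 0.11 and interferon genes −0.23 to 0.10.

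In pericytes of high_fibre offspring more RNA was counted of chaperones and of a fatty acid carrier, and less of 2 genes of organelle proteins. Whether the RNA of the carrier came from the pericytes themselves was not tested. Dnajb1, a co-chaperone, stood at 133 ± 40 CPM against 61.7 ± 1.57 CPM (SD, n = 2), a log2 fold of 1.09 (SE 0.201, adjusted p = 0.026, edgeR), and Hspa1b rose by 0.85 (adjusted p = 0.0489). Fabp4, the fatty acid carrier of capillary endothelium, rose by 0.56 (adjusted p = 0.0269), and C1qb rose by 1.46 (adjusted p = 0.0465). Igkc fell by 1.91 and Ighm, the immunoglobulin mu constant region, by 1.69 (adjusted p = 0.026 each), but 2 cells in each control_diet library held 93.2% and 96.5% of the Igkc UMIs and 78.4% and 100% of the Ighm UMIs. Chchd10, a mitochondrial protein, fell by 1.56 (adjusted p = 0.026), from 40.9 to 13.6 CPM, and Sdf2l1 fell by 1.30 (adjusted p = 0.0342), as it did in fibroblasts. Of 9288 genes tested in 1083 pericytes, 8 were called, 4 higher and 4 lower; 523 had an unadjusted p under 0.05 against 464 by chance, and the groups were apart for 34.9% of genes against 33.3% by chance. DESeq2 called 0 genes and limma-voom 6. Without high_fibre 1 Sdf2l1 (adjusted p = 0.122), Chchd10 (0.206), Dnajb1 (0.206), Hspa1b (0.229) and Fabp4 (0.769) lost their calls, without high_fibre 2 C1qb (0.104), and without control_diet 1 Chchd10 (0.0804), C1qb (0.508) and Sdf2l1 (0.541). Without high_fibre 2, control_diet 1 or control_diet 2, 44, 28 and 37 genes were called. Hba-a1 (1.63), Xist (−0.50) and Ddx3y (0.66) were not called, and simulations with no change called a median of 1 gene (0 to 5).

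Heat shock genes rose in pericytes, 17 of 19 above 0 with a median of 0.50 (camera adjusted p = 2.07e-10, adjusted p = 0.477 with an estimated correlation), 2 called over all genes and 5 higher adjusted over the list alone. Immediate early genes, which also answer to tissue dissociation, rose at a median of 0.31, 17 of 21 above 0 (camera adjusted p = 8.60e-07, adjusted p = 0.471 with an estimated correlation), with Cyr61 at 0.71 (adjusted p = 0.0641), Jun at 0.67 and Fos at 0.54; 5 were higher adjusted over the list alone. Ribosomal protein genes fell at a median of −0.12, 58 of 61 below 0 (1.78e-06, adjusted p = 0.471 with an estimated correlation). Lipid handling genes rose at 0.21 (0.00146) and cholesterol synthesis genes fell at −0.39 (0.00999), each with adjusted p = 0.471 with an estimated correlation; Cyp51 had −1.31, Fdft1 −1.21 and Mvd −1.20, while Nsdhl had 0.99. MHC class II genes were lower, 6 of 6 below 0 at a median of −0.87 (8.30e-06, adjusted p = 0.477 with an estimated correlation), opposite in sign to endothelial cells and fibroblasts. In the control_diet libraries 82.2% and 91.1% of the MHC class II UMIs of pericytes lay in 2 cells of each library, and without pericytes holding 3 or more Igkc UMIs the summed log2 fold turned from −1.22 to 1.44.

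The remaining passing lists in pericytes were erythroid transcripts (median 1.13, adjusted p = 8.30e-06), mitochondrially encoded transcripts (0.20, 0.000142), glucocorticoid-responsive genes (0.19, 0.00132), complement (0.07, 0.00174), the interferon response (−0.21, 0.00999), cell cycle genes (−0.27, 0.0253) and cytokines (0.49, 0.0287), among them Ccl2, a monocyte chemoattractant, at 1.20. They had adjusted p of 0.471 to 0.765 with an estimated correlation, and 13 of 31 lists passed in all. Adjusted over the list alone, erythroid transcripts had 4 higher members, mitochondrial 3, complement 2 and glucocorticoid, lipid and cytokine genes 1 each, while MHC class II had 2 lower and cholesterol and cell cycle genes 1 each. The heat shock median was 0.11 without high_fibre 1 and 0.72 without high_fibre 2. The tested members of a list can differ between fits without a library and the fit to all libraries. Leaving out each library in turn, the medians that moved by over 1.5 times ran as follows: heat shock 0.11 to 0.72, immediate early genes 0.10 to 0.29, MHC class II −1.27 to −0.36, erythroid transcripts 0.81 to 2.06, glucocorticoid genes 0.12 to 0.33, lipid genes 0.13 to 0.27, complement 0.06 to 0.46, interferon genes −0.55 to 0.04, cholesterol genes −0.20 to −0.02, cell cycle −0.26 to 0.15 and cytokines 0.28 to 0.54. Without high_fibre 2 the cholesterol (adjusted p = 0.331), complement (0.228), cytokine (0.0646) and cell cycle (0.0633) lists missed the threshold, and without control_diet 1 the lipid (0.194), complement (0.306), cytokine (0.705) and cell cycle (0.979, median 0.15) lists. Without high_fibre 1 the cell cycle list missed it (0.124) and the interferon list stood at −0.07 with its test in the other direction. Without control_diet 2 the cholesterol list missed it (0.446) and the interferon list turned to 0.04.

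**Figure D3:**
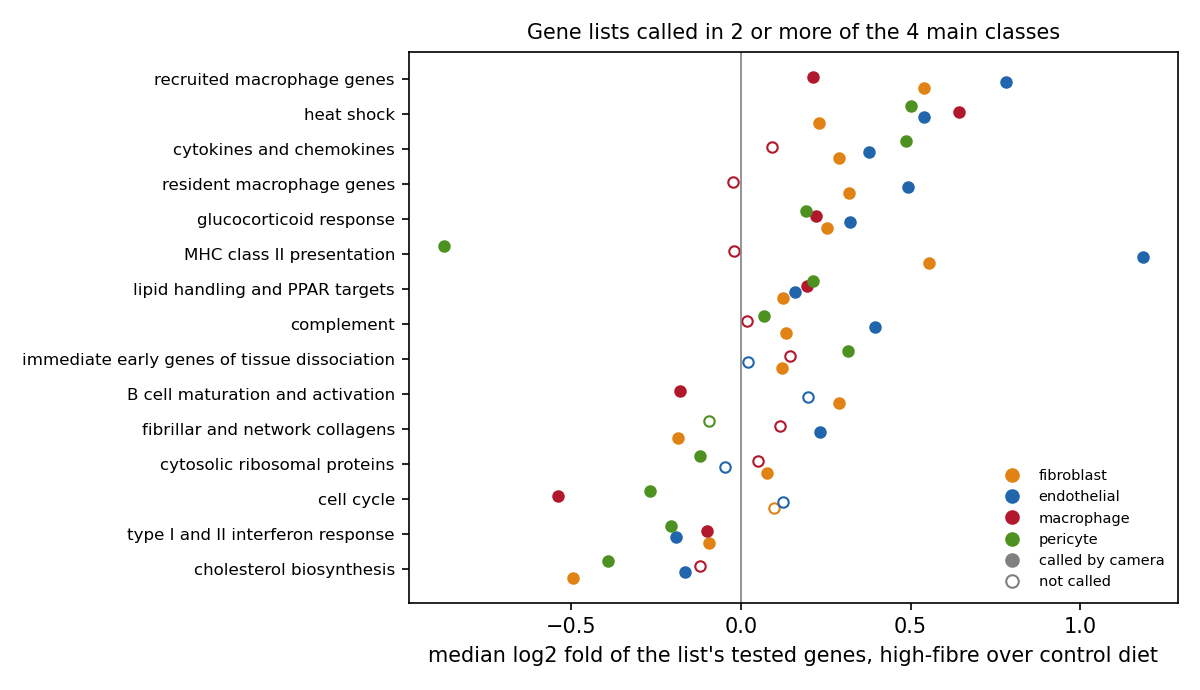
Median log2 fold (high-fibre over control diet) of the tested genes of 15 of the 16 lists called in 2 or more main classes, erythroid transcripts left out for their range; each point is 1 cell class, filled where camera called the list at its preset correlation. Heat shock medians lie between 0.23 and 0.64 in all 4 classes, and MHC class II genes at 1.18 in endothelial cells and −0.87 in pericytes.

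Hspa1b, an inducible chaperone, was the gene called in the most classes. It rose in pericytes, B cells by 1.86 (SE 0.229, adjusted p = 0.000105) and T cells by 1.85 (SE 0.25, adjusted p = 0.00518). Its log2 folds elsewhere were 1.09 in fibroblasts, 1.03 in smooth muscle, 0.74 in macrophages, 0.67 in endothelial cells and 0.54 in endocardial cells, none called (adjusted p of 0.647 to 1.00). In each main class the larger level was that of high_fibre 1, for example 1265 CPM against 848 CPM in high_fibre 2 in pericytes. C1qb and Sdf2l1 were each called in 2 classes. With no doublet removal 0 genes were called in B cells and in T cells, and DESeq2 called 0 in pericytes, which ends the Hspa1b calls there.

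The smaller classes added 9 genes. In T cells, the MHC class II gene H2-Ab1 fell by 2.63 (adjusted p = 0.000619), Cst3, cystatin C, by 1.40 (0.00722) and Ikzf2, a transcription factor of regulatory T cells, by 1.32 (0.0208). H2-DMb1 had 1 UMI in the high_fibre and 37 in the control_diet T cells, a rate ratio of 0.0186 (95% interval 0.000458 to 0.110, adjusted p = 0.00518). Few cells carried these transcripts: in control_diet 1 and 2, 94.2% and 97.9% of the H2-Ab1 UMIs lay in 2 cells and 1 cell, 87.5% and 100% of the H2-DMb1 UMIs in 1 cell each, and 82.8% and 63.1% of the Cst3 UMIs in 8 cells and 1 cell. In B cells Wfdc21 fell by 1.89 (adjusted p = 0.00268). In endocardial cells Edn1, the precursor of the vasoconstrictor endothelin, fell by 1.25 (SE 0.17, adjusted p = 0.00590), from 196 ± 28.6 to 81.3 ± 8.20 CPM (SD, n = 2). In smooth muscle Gadd45g fell by 1.87 (adjusted p = 0.017) and the interferon-induced Isg15 by 3.01 (0.0404), and Col3a1 rose by 2.14 (0.0428). None of these smooth muscle genes was called with DESeq2, with no doublet removal or with limma-voom. The numbers of genes tested were 6430 in T cells, 7348 in B cells, 8939 in endocardial cells and 5241 in smooth muscle, with 246, 279, 423 and 161 at an unadjusted p under 0.05. Without high_fibre 2, Ikzf2, Isg15 and Col3a1 lost their calls, without high_fibre 1 Edn1, and without control_diet 1 Isg15, Col3a1 and H2-DMb1.

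Among lists in the smaller classes, heat shock passed camera in B cells at a median of 0.87 (16 of 16 above 0, adjusted p = 2.14e-19), T cells at 0.64, endocardial cells at 0.18 and smooth muscle at 0.27, with adjusted p of 0.587 to 0.762 with an estimated correlation. MHC class II genes were lower in T cells at a median of −2.35 (adjusted p = 1.59e-16, adjusted p = 0.761 with an estimated correlation), where 4 cells of control_diet 1 and 1 cell of control_diet 2 held 95.4% and 97.9% of the UMIs of Cd74, H2-Aa, H2-Ab1 and H2-Eb1. Collagens fell in endocardial cells at −0.45 and rose in smooth muscle at 0.27, with adjusted p of 0.717 and 0.587 with an estimated correlation. Immediate early genes rose in B cells (0.41) and endocardial cells (0.41) and fell in smooth muscle (−0.97). In all 9 lists passed in B cells, 6 in T cells, 9 in endocardial cells and 8 in smooth muscle, with adjusted p of 0.587 to 0.855 with an estimated correlation.

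Genes tied to the metabolism of fibre products did not pass in any main class. The list of short-chain fatty acid activation and ketone metabolism had medians of 0.04 in fibroblasts (camera adjusted p = 0.578), 0.03 in endothelial cells (0.585), −0.12 in macrophages (0.0826) and −0.04 in pericytes (0.760). Histone deacetylases and sirtuins, enzymes that short-chain fatty acids can inhibit or whose cofactors follow metabolism, had medians of −0.03 (0.815), −0.02 (0.355), −0.02 (0.509) and 0.01 (0.893) in the same order. The receptors and transporters of short-chain fatty acids had fewer than 5 tested members in each class and were not tested as a list. In some lists that did not pass, the median, the mean and the test differed in sign. In fibroblasts matrix glycoproteins had a median of 0.01 and a test direction below 0, and hypoxia genes −0.03 and above 0. In endothelial cells the median was below 0 and the test above 0 for nitric oxide genes (−0.03) and NF-kappaB targets (−0.02), and immediate early genes had a median of 0.02 and a mean of −0.08.

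Where diet effects were set against each other between classes, few differed. The effect on Hspb1 was larger in fibroblasts than in endothelial cells by 0.71 on the log2 scale (SE 0.0545, adjusted p = 0.000195, limma), 1 of 3 genes called among 11026. Endothelial cells and pericytes differed for 6 of 8913 genes, 5 of them with the higher signed log2 fold in endothelial cells, and macrophages and pericytes for 2 of 8634. No gene differed between fibroblasts and macrophages, fibroblasts and pericytes, or endothelial cells and macrophages by limma, with 605, 604 and 474 genes at an unadjusted p under 0.05 and no other tool run. Leaving out single libraries moved these counts between 0 and 134.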

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

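The tests of high_fibre 1 alone and of immediate early genes below, the comparisons within each sex, the removal of cells rich in immune transcripts and the UMI window were chosen after the data were seen. Diet effects were set against each other between main classes, and between cells with Xist and cells with Y-linked transcripts, and the results here are those whose difference passed the test of the difference.

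Hspb1, a small heat shock protein, had a larger effect in fibroblasts (log2 fold 1.06) than in endothelial cells (0.36), a difference of 0.71 (adjusted p = 0.000195). Oaf differed between the same classes by −1.26 (adjusted p = 0.00230), at 0.01 in fibroblasts and 1.40 in endothelial cells, and Dusp1 by 0.50 (adjusted p = 0.0232). Between endothelial cells and pericytes, Igkc differed by 3.64 (adjusted p = 0.00354) and H2-Aa by 2.22 (0.0250). In control_diet pericytes 2 cells of each library held 93.2% and 96.5% of the Igkc UMIs and 91.3% and 91.1% of the H2-Aa UMIs. Without pericytes holding 3 or more Igkc UMIs the log2 fold of the MHC class II sum was 1.44 in pericytes, against 1.22 in endothelial cells. Apoe, apolipoprotein E, differed by −0.84, Oaf by 1.59, Lpl by 0.65 and Pde4b by 1.04 between those 2 classes (adjusted p = 0.0480 each). Between macrophages and pericytes, Ighm differed by 1.38 (adjusted p = 0.0127) and Fcer1g by −1.18 (0.0435). In control_diet pericytes 78.4% and 100% of the Ighm UMIs lay in 2 cells of each library.

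Between the sexes, the diet effect of female cells minus that of male cells in fibroblasts was −1.32 for Gm47283 (adjusted p = 0.00123), −1.43 for Angptl4 (0.00772), −1.08 for Wisp2 (0.00772) and 1.11 for Col27a1 (0.0165). In endothelial cells it was −2.86 for Cytl1 (adjusted p = 0.00116), −1.06 for Gm47283 (0.00936) and 0.73 for Fos (0.0311). In macrophages it was −1.30 for Hspb1 (adjusted p = 0.000140), and in pericytes 1.02 for Cxcl12 and −0.94 for Fabp4 (0.0254 each). By limma these were 4 of 11927 genes in fibroblasts, 3 of 10083 in endothelial cells, 1 of 9684 in macrophages and 2 of 6327 in pericytes. In that order 464, 416, 385 and 319 genes had an unadjusted p under 0.05. This was no clear excess over the share of 0.05 that chance gives.

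Macrophage and MHC class II transcripts were higher in endothelial cells of the high_fibre libraries. Doublets of endothelial cells with macrophages are argued against as the whole cause: without endothelial cells holding 3 or more macrophage marker UMIs the C1q sum had a log2 fold of 1.216 (SE 0.146), against 1.36 with them; fibroblast transcripts in endothelial cells had 0.73 (SE 0.289), not called. Free RNA from one immune source reaching every droplet alike cannot be told apart from diet. The ratio of MHC class II to C1q UMIs in endothelial cells lay within a mean log2 of 0.026 (SE 0.044) of that in fibroblasts. It lay above that in macrophages by 0.557 (SE 0.033), so the kept macrophages as a whole do not match such a source. Single macrophage clusters, such as cluster 2 led by H2-Eb1, were not compared. The ratio over that in pericytes, −1.485 (SE 0.723), met the bound set beforehand for excluding free RNA, but rests on 2 cells in each control_diet library that held 82.2% and 91.1% of the MHC class II UMIs, and was 0.113 (SE 0.076) without pericytes holding 3 or more Igkc UMIs. A biological effect of maternal diet on immune transcripts in endothelial cells was not tested apart from these.

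Heat shock genes were higher in the high_fibre libraries in all 4 main classes. Dissociation stress as read by the immediate early genes cannot be told apart from diet: their mean level was highest in high_fibre 1 in 3 of 4 main classes, but in endothelial cells it was 7.23 there and 7.37 in control_diet 1 (log2 CPM). One library, high_fibre 1, carried most of the rise: without it the median kept a share of 0.065 in endothelial cells, 0.076 in fibroblasts, 0.225 in pericytes and 0.291 in macrophages. The mean level of the list in high_fibre 2 still lay above both control_diet libraries in each main class. In endothelial cells these levels were 7.43 against 7.39 and 7.35 (log2 CPM). Why high_fibre 1 stood highest was not settled. A different mix of female and male cells cannot be told apart from diet, since more than 50% of the median was kept in both female and male cells in 1 of 4 main classes, the libraries differ in sex mix, and heat shock genes were lower in female than in male cells in all 4 (medians −0.28 to −0.31). Maternal diet itself remains among the open explanations, untested.

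Cholesterol synthesis genes and the endoplasmic reticulum genes Sdf2l1, Creld2 and Manf were lower in fibroblasts of the high_fibre libraries. A different mix of fibroblast clusters is argued against, since with equal weight to each of 4 clusters the smaller share of the medians kept was 0.888. Within each of these clusters the cholesterol median lay below 0, from −0.23 in cluster 4 to −0.65 in cluster 7, against −0.50 in all fibroblasts. Fibroblast cluster 22, with 9 cells in control_diet 2, was left out. A different mix of female and male cells is argued against, with a lowest share of 0.828 kept, for the endoplasmic reticulum genes in female cells. A different UMI depth per fibroblast is argued against, with a lowest share of 0.828 kept, for cholesterol genes among fibroblasts of 8000 to 16000 UMIs. Batches of handling were not tested because the labels give none, and an effect of maternal diet remains open and untested.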

How the results depend on the processing

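The alternatives restricted to cells of one sex or without low-UMI clusters were chosen after seeing the data. The cause of the changes below was not tested. Of 550 values of called genes under the alternatives, 394 kept their call and 156 lost it, with 0 in the other direction. Of 497 values of passing lists 333 kept it, 151 lost it and 13 turned direction, and of 66 values of differences between classes 48 kept it and 18 lost it. Of 170 shares 150 kept their direction, with 0 called under any alternative. Uncalled named genes (228) gave 3471 values, of which 491 moved by more than 1 SD, 102 took the other sign and 199 were newly called. Leaving out a library leaves 1 in its group, which is assumed to vary like the other group. DESeq2 size factors gave 1 higher and 3 lower genes in fibroblasts against 0 and 3, and 3 and 1 in endocardial cells against 0 and 1. The counts below are of any called genes and need not be the same genes. Of the 8 genes called in pericytes, 0 kept their call in female cells only and 1 in male cells only. Of the 3 in smooth muscle, 0 kept it with DESeq2, no doublet removal or limma-voom.

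Fibroblasts had 3 called genes, against 42 with DESeq2, 256 with no low-count filter, 5 with counts thinned to the lowest library, 5 with limma-voom, 0 in female cells only, 27 in male cells only, and 0 to 218 when leaving out a library. Endothelial cells had 15, against 102 with no low-count filter, 8 with no doublet removal, 9 with a mitochondrial share at most 10%, 7 in female cells only, 6 in male cells only, and 7 to 113 when leaving out a library. Macrophages had 0, against 1 with DESeq2, 50 with no low-count filter, 1 in female cells only, and 0 to 8 when leaving out a library. Pericytes had 8, against 0 with DESeq2, 26 with no low-count filter, 5 with a mitochondrial share at most 10%, 1 with thinned counts, 2 at clustering resolution 0.5, 2 in female cells only, 5 in male cells only, 5 with low-UMI clusters left out, and 10 to 44 when leaving out a library.

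B cells had 2 called genes, against 1 with DESeq2, 19 with no low-count filter, 0 with no doublet removal, and 10 to 36 when leaving out a library. T cells had 5, against 3 with DESeq2, 37 with no low-count filter, 0 with no doublet removal, 8 with a mitochondrial share at most 10%, 2 with thinned counts, 3 with limma-voom, and 36 to 71 when leaving out a library. Endocardial cells had 1, against 4 with DESeq2 size factors, 46 with no low-count filter, 10 with no doublet removal, 11 with thinned counts, 4 with limma-voom, and 3 to 92 when leaving out a library. Smooth muscle had 3, against 1 with DESeq2, 16 with no low-count filter, 0 with limma-voom, and 5 to 79 when leaving out a library.

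With the repeat number as a replicate block, called genes numbered 25 in fibroblasts, 93 in endothelial cells, 11 in macrophages, 25 in pericytes, 20 in B cells, 23 in T cells, 14 in endocardial cells and 7 in smooth muscle. Under the block, differences between classes numbered 54 (fibroblast and endothelial), 20 (fibroblast and macrophage), 13 (fibroblast and pericyte), 64 (endothelial and macrophage), 31 (endothelial and pericyte) and 19 (macrophage and pericyte), and the log2 share ratio was 0.0177 for fibroblasts and −0.420 for neutrophils. Libraries of the same number deviated together with correlations of 0.529 in macrophages, 0.223 in endothelial cells, 0.199 in fibroblasts and 0.0993 in pericytes, which with 2 numbers does not show that the numbers pair the libraries.

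Passing lists numbered 0 in each main class with the correlation estimated per list. They numbered 11 in fibroblasts of male cells only (17 in all cells), 6 in endothelial cells of female cells only (13), 6 in macrophages of male cells only (13), and 7 and 4 in pericytes of female and male cells only (13). Leaving out a library gave 13 to 21 lists in endothelial cells and 4 to 17 in macrophages. Leaving out a library gave 0 to 53 differing genes between fibroblasts and endothelial cells (3 with all), 0 to 134 between fibroblasts and macrophages (0), 3 to 53 between fibroblasts and pericytes (0), 1 to 19 between endothelial cells and macrophages (0), 2 to 106 between endothelial cells and pericytes (6) and 6 to 18 between macrophages and pericytes (2). The last was 1 with a prior count of 0.5.

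List medians or test directions that turned were, in female cells only, 0.0439 for B cell genes in fibroblasts, 0.43 for erythroid transcripts in macrophages and 0.0183 for interferon genes in macrophages. In male cells only they were 0.78 for erythroid transcripts and −0.00353 for interferon genes in macrophages and 0.0494 for complement in pericytes. Leaving out a library, medians ran from −0.0778 to 0.33 for immediate early genes in fibroblasts, −0.0939 to 0.52 for glucocorticoid and −0.29 to 0.55 for NF-kappaB genes in macrophages, −5.55 to 0.11 for erythroid and −0.23 to 0.10 for interferon genes in macrophages, and −0.55 to 0.0399 for interferon genes in pericytes.

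Log2 share ratios that turned were −0.0104 for NK cells and 0.00274 for fibroblasts with a mitochondrial share at most 10%, 0.00896 for fibroblasts, 0.29 for lymphatic cells and 0.0334 for smooth muscle with no doublet removal, and 0.0726 and 0.0956 for fibroblasts with a minimum of 1000 UMIs and with low-UMI clusters left out. Leaving out a library they ran from −0.31 to 0.61 for NK cells, −0.19 to 0.60 for T cells, −0.22 to 0.26 for fibroblasts, −1.91 to 0.57 for lymphatic cells, −3.01 to 0.98 for neutrophils and −1.06 to 0.49 for smooth muscle.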

Other observations

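The comparison of female and male cells and the split by repeat number were chosen after the data were seen. Fibroblasts of the 2 sexes differed: with each library as its own block, 138 of 11927 genes were called by edgeR, 52 higher in female cells (Xist without Y-linked UMIs) and 86 higher in male cells. Of these, 9 lie on the X chromosome, 7 of them higher in female cells, and 129 on autosomes. The X-linked Eif2s3x (log2 fold 0.77), Kdm6a (0.71), Kdm5c (0.54) and Ddx3x (0.46), which escape X inactivation, were higher in female fibroblasts. Serpina3n, a protease inhibitor of the acute phase, was lower in female fibroblasts (−1.22, adjusted p = 0.000272), as were Ptgs2, the inducible cyclooxygenase (−1.16), Cyp1b1 (−1.29), Penk (−0.83), Serpine2 (−0.71) and the glucocorticoid-induced Fkbp5 (−0.90) and Mt2 (−0.63). Eef1a2 (1.56), Mgp (0.42) and Lum (0.41) were higher in female fibroblasts. These genes were chosen after their values were seen. Sex was called from detected UMIs, and male-called fibroblasts were deeper in each library. In high_fibre 1 their median was 12980 UMIs, against 10214.5 in female-called fibroblasts. Sex, depth and the animals behind each sex cannot be told apart here.

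Glucocorticoid-responsive genes were lower in female fibroblasts, 16 of 18 below 0 with a median of −0.35 (camera adjusted p = 2.57e-14, adjusted p = 0.476 with an estimated correlation), as were heat shock genes, 19 of 20 below 0 with a median of −0.30 (2.21e-11, adjusted p = 0.571 with an estimated correlation). In macrophages glucocorticoid-responsive genes were higher in female cells, at a median of 0.10 (camera adjusted p = 0.0181, adjusted p = 0.828 with an estimated correlation). Heat shock genes were lower in female cells also in endothelial cells (−0.30, camera adjusted p = 9.18e-05), macrophages (−0.31, 2.21e-12) and pericytes (−0.28, 7.52e-07), with adjusted p of 0.616 to 0.762 with an estimated correlation. MHC class II genes were lower in female macrophages, at a median of −0.31 (camera adjusted p = 2.35e-15, adjusted p = 0.616 with an estimated correlation). Immediate early genes of tissue dissociation were lower in female fibroblasts (−0.12, 0.00108) and higher in female pericytes (0.33, 3.56e-15), with adjusted p of 0.571 and 0.120 with an estimated correlation. Mitochondrial (0.06, 0.0141) and cardiomyocyte (0.47, 0.00748) transcripts were higher in female fibroblasts, each with adjusted p = 0.618 with an estimated correlation. Mitochondrial transcripts were also higher in female pericytes (0.18, camera adjusted p = 3.67e-06, adjusted p = 0.648 with an estimated correlation). In fibroblasts, collagens were lower by a median of −0.21 (2.27e-06) and NF-kappaB targets by −0.19 (1.02e-07), each with adjusted p = 0.571 with an estimated correlation. Endothelial cells had 14 of 10083 genes called between the sexes, macrophages 13 of 9684 and pericytes 6 of 6327. The 2 sex labels can be swapped within the 4 libraries in only 8 ways, too few for a share under 0.05. The real labels were the 1 of 8 that called the most genes in each class, 138 against at most 0 for the others in fibroblasts, 14 against 5 in endothelial cells, 13 against 6 in macrophages and 6 against 3 in pericytes.

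Macrophages differed between the libraries of repeat 1 and those of repeat 2, with 158 genes called between them by edgeR against 0 between the diets. Higher in repeat 1 were Cxcl10 (log2 fold 1.26), the NF-kappaB inhibitors Tnfaip3 (1.40) and Nfkbia (1.30), Atf3 (1.18), Ier3 (1.02) and Egr1 (0.93). Immediate early genes had a median of 0.60 (camera adjusted p = 1.67e-42, adjusted p = 0.473 with an estimated correlation) and NF-kappaB targets 0.94 (7.60e-33, adjusted p = 0.473 with an estimated correlation). The split by repeat number called 6 genes in fibroblasts, 8 in endothelial cells, 1 in pericytes, 19 in endocardial cells, 15 in B cells, 7 in T cells and 0 in smooth muscle. The remaining split of the libraries (high_fibre 1 and control_diet 2 against the others) called 26 genes in T cells and 0 in every other tested class. The diets themselves differed in 1 endocardial, 2 B cell, 5 T cell and 3 smooth muscle genes, so calls in the smaller classes did not exceed those of other splits of the libraries, smooth muscle apart. Nor did they in fibroblasts (3 between the diets, 6 by repeat number) or macrophages. They did in endothelial cells (15 and 8) and pericytes (8 and 1). With 3 splits the diets come first by chance with a share of 0.333, so this order does not show a diet effect. Simulations with no change called 1 to 16 genes in endothelial cells, a range that holds 15, and 0 to 5 in pericytes.

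Slc15a2 had log2 folds between the diets of −3.14 in fibroblasts (adjusted p = 0.134) and −2.91 in B cells (0.188), beside its call in endothelial cells, but −0.49 in macrophages (1.00), and the endothelial fold minus the macrophage fold was −2.85 (adjusted p = 0.0581). Rbm3 had log2 folds of 0.58 in fibroblasts (adjusted p = 0.134), 0.47 in endothelial cells (0.251), 0.67 in macrophages (1.00) and 0.46 in pericytes (0.565), and was not called in any of them.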
